A study of Mus musculus with 9 samples.

How the data were processed

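ATAC-seq was analysed in 9 libraries of sorted mouse embryonic stem cells, 3 each of NanogKO, NanogKO:Esrrb and NanogKO:Esrrb:Nanog. The deposited count table held raw read counts per region, whole numbers with no normalization, for 157497 regions and the 9 libraries. Each group also had a deposited list of peak intervals, and the score of each peak is the authors' own value from their peak caller, 13 or higher in every list, used here only to rank peaks within their list. Coordinates were on mm10, per the submitters' processing notes, which also name bcl2fastq 2.19.1, cutadapt, Bowtie2, SAMtools 1.4.1, deepTools 4.4.0, MACS2 2.2.0 and bedtools 2.26.0 without saying what each did. The tool that counted the reads is not given in the sources used here, nor is any shift of reads for the transposase, any removal of duplicate reads or any mapping filter. Merging the 3 peak lists gave the counted regions exactly, so regions open only outside those lists were not counted. Coordinates are printed counted from 1.

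Counts were tested with edgeR 4.0.16 in R 4.3.3. All 9 libraries entered 1 fit of group means with TMM factors, and regions passing filterByExpr (157439) were tested with the quasi-likelihood F test, which left 6 residual degrees of freedom. A region was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p for a single region comes from this test. CPM values are counts scaled to library totals with TMM factors, and log2 CPM used a prior count of 2. Principal components were taken from log2 CPM of all tested regions. A fold for regions with 0 counts in a group was set against a floor of 3 counts over the group.

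Regions were assigned to the nearest protein-coding gene of the RefSeq annotation GRCm38.p6, the assembly of mm10, and 85.1% had one within 50 kb. That table gives no strand, so distances run to the gene's span and not to its transcription start as the design had stated. The regions of a list lie in or within 50 kb of its genes. For a single gene, "near" means outside its span, and "in" a gene means within it, exons and introns not told apart. The 14 gene lists (naive pluripotency, general pluripotency, formative and primed pluripotency, primitive endoderm, mesendoderm, neural, trophoblast, ERK feedback, LIF and STAT3 targets, WNT targets, germline and early cleavage, fibroblast, endothelium and blood, and housekeeping) held 253 entries and 237 distinct genes, all matched, with 16 genes in more than 1 list. Pecam1, the gene of a sort marker, is in the endothelium and blood list, and Pdgfra, the gene of the other marker, in the primitive endoderm list. Lists were tested over regions within 50 kb with camera of limma 3.58.1 at its preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 14 lists of a comparison. Camera sets a list against the other regions, and fry asks whether its regions move one way. Regions that share a gene are not independent.

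The groups, the tests, the lists, the alternatives and the rule for named regions were chosen before the data were examined. By that rule a comparison names the region of smallest p at Nanog and at Esrrb, and the 5 largest rises and 5 largest falls among called regions at or above the median abundance whose libraries do not overlap between groups. It also names the 2 called regions of smallest p in each list, with at most 1 region per gene. Fold changes are log2 with standard errors unless called fold, and SD marks the spread of CPM in a group.

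The replicate numbers were checked for pairing by correlating the deviations of libraries from their group means. Libraries with the same number correlated at 0.117 to 0.152 between NanogKO and NanogKO:Esrrb and at 0.105 to 0.146 between NanogKO:Esrrb and NanogKO:Esrrb:Nanog, so the numbers were taken to pair these groups. Between NanogKO and NanogKO:Esrrb:Nanog they correlated at 0.002 to 0.136 and were not taken to. Pairing in both other comparisons would pair these groups as well, so the values do not settle the pairing. Libraries with different numbers correlated at -0.098 to 0.045. Deviations within a group cancel out, so these values are not independent of those for the same number. The pairing comes from these values, since the labels name no shared culture or day. The sample numbers in the titles do run through the groups within each replicate number in turn. The main tests did not use the pairing, and the replicate block is given as an alternative. No 2 libraries of a group were copies, with a chi-square per region of 3.55 to 9.49.

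The fits were tested on simulated counts with 200 changed regions. At 1.5-fold and 2-fold, 13% and 63% of changed regions were recovered over 157335 regions for NanogKO:Esrrb against NanogKO, with 4 false calls. For NanogKO:Esrrb:Nanog against NanogKO, 22% and 70% were recovered over 157339 regions with 5 false calls, and for NanogKO:Esrrb:Nanog against NanogKO:Esrrb 13% and 69% over 157330 regions with 7 false calls. In the data 58223, 77576 and 38712 regions were called in these comparisons, far more than the 200 simulated. Recovery and false calls at an adjusted p depend on how many regions change, so these rates do not describe the fits of the data.

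The alternatives were DESeq2 size factors, library totals, loess offsets, the DESeq2 1.42.0 Wald test, limma's voom, no filter, at least 20 counts in 3 libraries, the replicate block, only the 6 libraries compared, a test against a 1.5-fold change, an adjusted p under 0.01, autosomes alone, and each library left out in turn. For lists, gene distances of 10 and 100 kb, regions within 1 kb of a gene end and the other tests were tried, and after the results were seen the lists less the regions of Esrrb and Nanog. For peak lists, an overlap of 50% of both lengths and peaks at or above their list's median score were tried. Overlaps were computed with bedtools 2.31.1, and tables and figures with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Motif comparisons and corrections for GC content need a genome sequence and were not run.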

Results

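Chromatin accessibility was measured by ATAC-seq, an assay in which a transposase places sequencing adapters in open DNA, in mouse embryonic stem cells. The 9 libraries fell into 3 groups of 3. By their labels, NanogKO cells were a Nanog knockout, NanogKO:Esrrb cells had Esrrb added, and NanogKO:Esrrb:Nanog cells had both Esrrb and Nanog added. NANOG and ESRRB are transcription factors of the pluripotency network. All cells grew with 10% serum and 1000 U/ml of leukaemia inhibitory factor (LIF), a cytokine that sustains self-renewal, and were sorted for PECAM, present on undifferentiated cells, and against PDGFRA, a marker of primitive endoderm. The series title places ESRRB between self-renewal and differentiation, and the 3 comparisons ask how accessibility differed with the labelled Esrrb and Nanog. The labels give NanogKO one cell line name and both other groups another, shared name, so each comparison with NanogKO also compared differently named lines. The sample titles give each of the 3 groups a code of its own, whose meaning is not stated, so every comparison is also one between differently coded cells. The series design counts 12 samples, and those beyond the 9 were not analysed here.

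Reads were counted in 157497 regions with a median length of 345 bp. Of these regions, 55.7% lay within a protein-coding gene. Total counts were 41334847, 52871542 and 47360197 in NanogKO replicates 1 to 3, 49870948, 58096403 and 55227844 in NanogKO:Esrrb, and 52468157, 35545030 and 58520948 in NanogKO:Esrrb:Nanog. The median count per region ranged from 96 to 175 among libraries. The first principal component held 63.6% of the variance and ordered the groups, with NanogKO between -209.9 and -188.2, NanogKO:Esrrb between 25.4 and 60.3, and NanogKO:Esrrb:Nanog between 136.4 and 179.9. On the next component, with 15.5% of the variance, NanogKO:Esrrb:Nanog replicate 3 stood at 5.5 while replicates 1 and 2 stood at 87.6 and 101.4. Within groups, log2 CPM (counts scaled to library size) correlated across regions with Pearson's r of 0.964 to 0.983. The labels do not say that replicates were separate cultures, so all p-values measure the spread between these libraries, which may be technical.

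**Figure D1:**
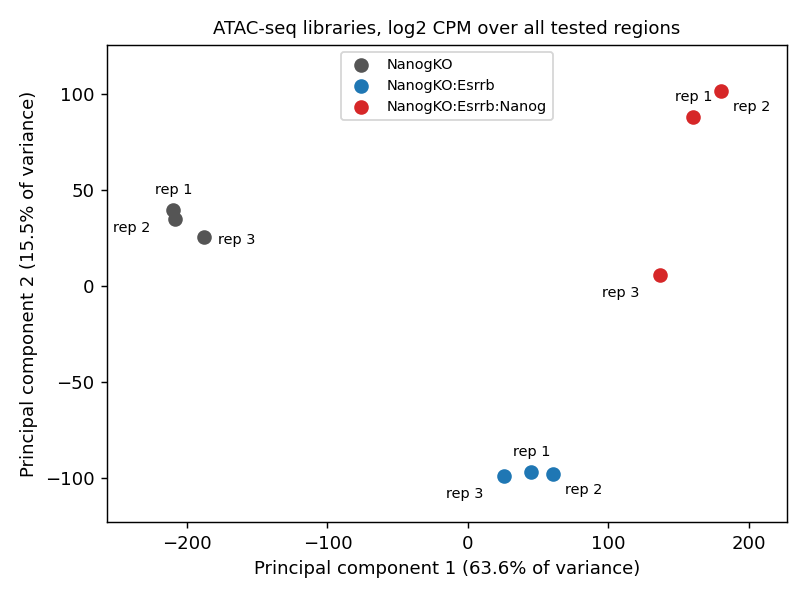
Principal components of log2 CPM for the 9 libraries, with component 1 (63.6% of the variance) on the x axis and component 2 (15.5%) on the y axis; each point is 1 library, coloured by group and marked with its replicate number. The groups follow one another along component 1, and NanogKO:Esrrb:Nanog replicate 3 lies at 5.5 on component 2, below the other two libraries of its group.

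The loci named in the labels were examined in every library first. Around Esrrb (gene 26380, mm10 chr12:86361117-86521628), 31 regions lay in the gene or within 10 kb. In NanogKO:Esrrb, 19 of them were higher and 2 lower than in NanogKO, with a median log2 fold change of 0.69. In NanogKO:Esrrb:Nanog, 25 were higher and 1 lower than in NanogKO, with a median of 1.18. Between these groups, 23 were higher with Nanog, with a median of 0.73. The region with the smallest p against NanogKO (chr12:86503894-86504645, within the gene) had 3.76, 4.24 and 5.29 CPM in NanogKO, 20.3, 22.2 and 18.5 CPM in NanogKO:Esrrb, and 38.6, 31.6 and 37.8 CPM in NanogKO:Esrrb:Nanog. One region in the gene (chr12:86429379-86429562) fell, with log2 fold changes of -1.68 ± 0.26 (SE) and -2.22 ± 0.28 against NanogKO. How Esrrb was added is not given in the labels. Reads from added sequence can fall in exons and were not told apart from reads of the gene's own locus.

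At Nanog (gene 71950, chr6:122707489-122714633), 5 regions lay in the gene or within 10 kb. The region within the gene (chr6:122713174-122713525) had 0.902, 0.937 and 1.56 CPM in NanogKO, 3.02, 3.83 and 4.02 CPM in NanogKO:Esrrb, and 4.25, 4.49 and 6.17 CPM in NanogKO:Esrrb:Nanog. Its log2 fold change was 1.67 ± 0.22 in NanogKO:Esrrb (adjusted p = 1.2e-06) and 2.13 ± 0.22 in NanogKO:Esrrb:Nanog (9.5e-09), both against NanogKO. Between the groups with and without added Nanog it was 0.46 ± 0.20, which did not pass the test (adjusted p = 0.091). A region 865 bp outside the gene (chr6:122715498-122716465) fell from 12.4 ± 0.76 to 8.59 ± 1.5 CPM (SD, n = 3) when Nanog was added, a log2 fold change of -0.52 ± 0.13 (adjusted p = 0.0051). The labels do not give the deleted part of Nanog, and reads from added Nanog sequence were not told apart either. These regions therefore check the genotypes only in part.

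**Figure D2:**
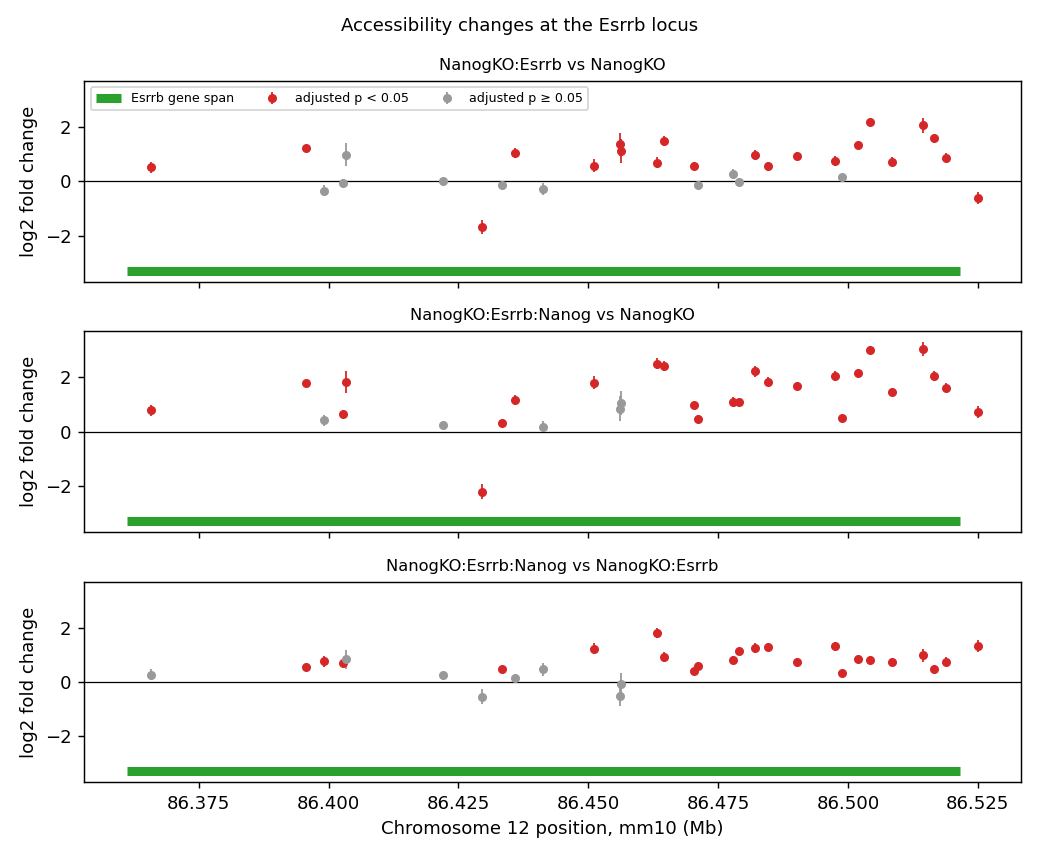
Regions in and around Esrrb on chromosome 12 (x axis, position in Mb, mm10) with their log2 fold change (y axis) in each of the 3 comparisons; points are regions, red where called and grey where not, bars are standard errors, and the green bar is the gene's span. Most regions lie above 0, and the region at 86503894 was 4.58-fold and 8.11-fold higher than in NanogKO.

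In NanogKO:Esrrb cells, regions near genes of naive pluripotency, the state of undifferentiated embryonic stem cells, rose together compared with NanogKO: 185 of 374 regions were higher and 22 lower, or 189 and 23 when adjusted over the list alone (adjusted p = 4e-09 for the list by camera, and adjusted p = 0.18 with an estimated correlation). Regions near targets of LIF and STAT3 signalling rose as well, with 93 of 231 higher and 15 lower (97 and 15 adjusted over the list alone; adjusted p = 2.9e-05, and adjusted p = 0.18 with an estimated correlation). Regions near neural genes fell, with 53 of 183 lower and 16 higher (55 and 16 adjusted over the list alone; adjusted p = 0.00082, and adjusted p = 0.18 with an estimated correlation). The median log2 fold changes of these lists were 0.43, 0.30 and -0.25. The naive and LIF lists share 5 genes (Klf4, Klf5, Tfcp2l1, Gbx2 and Stat3), and the naive list holds Nanog and Esrrb themselves.

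Among naive genes, a region in Jam2, which encodes a junctional adhesion molecule, rose 4.51-fold (chr16:84778713-84780239, log2 fold change 2.17 ± 0.13, from 9.96 ± 1.2 to 45.0 ± 5.0 CPM, SD, n = 3). A region 90054 bp from Tbx3, a T-box factor of naive cells, and so beyond the 50 kb of the list, rose 12.5-fold (chr5:119579799-119580480, 3.65 ± 0.21). Among LIF targets, a region near Klf5, a Krüppel-like factor of self-renewal, rose from 12.9 ± 1.0 to 39.3 ± 3.9 CPM (chr14:99324281-99325180, 1.61 ± 0.12). A region near Cish, a feedback inhibitor of cytokine receptors, fell from 14.2 ± 0.87 to 2.73 ± 0.41 CPM (chr9:107305327-107306330, -2.38 ± 0.16). Among neural genes, regions in Meis2, a homeobox factor, and Map2, a neuronal microtubule protein, fell (-2.48 ± 0.30 and -1.46 ± 0.21). Adjusted p for these 6 regions lay between 1.6e-12 and 2.9e-06.

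These 3 lists passed camera, the test of whole lists, at its preset correlation, adjusted over 14 lists. With an estimated correlation, 0 of the 14 lists passed camera, 2 had an unadjusted p below 0.05, and fry, which asks whether a list moves one way, called 11. Among regions within 1 kb of a gene end, where camera was run alone, 0 passed and 3 had an unadjusted p below 0.05, and the naive, neural and LIF lists had adjusted p = 0.05, 0.05 and 0.87, none under the threshold. Their median log2 fold changes there were 0.24, -0.25 and 0.04, against 0.43, -0.25 and 0.30 within 50 kb. Over the alternatives tested with camera, adjusted p ran from 1.3e-09 to 0.18 for the naive list, from 4.7e-06 to 0.87 for the LIF list and from 7.4e-05 to 0.18 for the neural list. Within 10 kb of a gene 7 lists passed, these 3 and general pluripotency (higher, 0.011), ERK feedback (higher, 0.047), mesendoderm (lower, 0.021) and trophoblast (lower, 0.033). Within 100 kb, ERK feedback passed besides these 3 (higher, 0.027). Less the regions of Esrrb and Nanog, the naive list had 159 of 324 regions higher and 20 lower (adjusted p = 7e-09, and 0.18 with an estimated correlation).

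With the replicate number as a block, 6 lists passed: besides these 3, targets of ERK feedback (higher, adjusted p = 0.046), germline and early cleavage genes (higher, 0.046) and mesendoderm (lower, 0.047). Without NanogKO replicate 3, germline and early cleavage genes (0.034) and mesendoderm (0.049) passed as well. Germline and early cleavage genes also passed without NanogKO:Esrrb replicate 2 (0.021), and ERK feedback targets without NanogKO:Esrrb replicate 3 (0.031). Over the alternatives tested with camera, their adjusted p ran from 0.027 to 0.66 for ERK feedback, from 0.021 to 0.87 for germline and early cleavage, and from 0.021 to 0.18 for mesendoderm. Fry, which tests a list against no change and not against other regions, gave 0.0016, 0.00089 and 0.0016.

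The other 11 lists did not pass within 50 kb in this comparison, with adjusted p from 0.053 to 0.99. ERK feedback targets had 94 regions higher and 35 lower of 307, germline and early cleavage genes 10 and 2 of 31, and mesendoderm 11 and 18 of 128. Genes of general pluripotency had 67 higher and 28 lower of 212, formative and primed pluripotency 69 and 71 of 322, primitive endoderm 63 and 48 of 268, and trophoblast 37 and 44 of 218. WNT targets had 19 higher and 34 lower of 152, fibroblasts 10 and 17 of 97, endothelium and blood 29 and 36 of 184, and housekeeping genes 26 and 20 of 109. The median of the primitive endoderm list was -0.01 and its mean 0.06. No count of these 11 lists shifted by more than 3 regions when adjusted over the list alone.

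Single regions in these lists changed in both directions. A region in Lin28a, an RNA-binding protein that blocks let-7 maturation, fell 7.97-fold (chr4:134006906-134007144, -2.99 ± 0.22), while one in Sall4, a zinc finger factor of pluripotency, rose (1.53 ± 0.14). A region near Foxd3 rose (2.49 ± 0.17) and one near Grhl2, an epithelial factor, fell (-1.71 ± 0.16). Of the basement membrane genes, Col4a2 held a region that rose (2.51 ± 0.21), and near Lamb1 one fell (-2.51 ± 0.19). Regions at the mesendoderm genes Lefty1, a NODAL antagonist, and Foxa2 fell (-1.42 ± 0.13 and -1.58 ± 0.19). A region near Dusp6, an ERK phosphatase, rose (1.61 ± 0.13) and one near Etv5, an ETS factor, fell (-2.79 ± 0.28). Regions near Tfap2a and in Fgfr2, both of the trophoblast list, moved by 1.82 ± 0.18 and -3.32 ± 0.22. Near Notum, which inactivates WNT ligands, a region rose (1.59 ± 0.15), and in Znrf3, which removes WNT receptors, one fell (-1.96 ± 0.24). Regions near Tcstv1 and in Mael rose (1.67 ± 0.18 and 1.95 ± 0.22), as did regions at Col5a1 and Thy1 of the fibroblast list (1.80 ± 0.18 and 1.77 ± 0.20). Regions near Tal1 and Pecam1 fell (-1.84 ± 0.16 and -1.89 ± 0.18), PECAM being a marker of the sort. Regions near the housekeeping genes Eif4a2 and Ywhaz rose (2.00 ± 0.14 and 1.64 ± 0.17). All regions named for this comparison had adjusted p at or below 2.9e-06.

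Over all regions, 31482 were higher and 26741 lower in NanogKO:Esrrb than in NanogKO, or 37% of the 157439 tested (edgeR's quasi-likelihood test). By more than 2-fold, 13170 were higher and 9463 lower. The regions that rose were seldom near gene ends, 6.1% lying within 1 kb of one, against 11.9% of those that fell and 18% of those not called. Besides the region at Tbx3, the largest rises by the naming rule lay 135802 bp from LOC108167368 (3.67 ± 0.20), in Lars, a leucyl-tRNA synthetase (3.54 ± 0.25), in Sap30bp (3.37 ± 0.19) and in Rcn1 (3.37 ± 0.28). The largest falls on autosomes lay near 1520401A03Rik (-4.10 ± 0.17), in Arsg, a lysosomal sulfatase (-4.03 ± 0.24), near Zfp341 (-3.92 ± 0.21) and 50580 bp from Pth2r, a parathyroid hormone receptor gene (-3.90 ± 0.23).

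**Figure D3:**
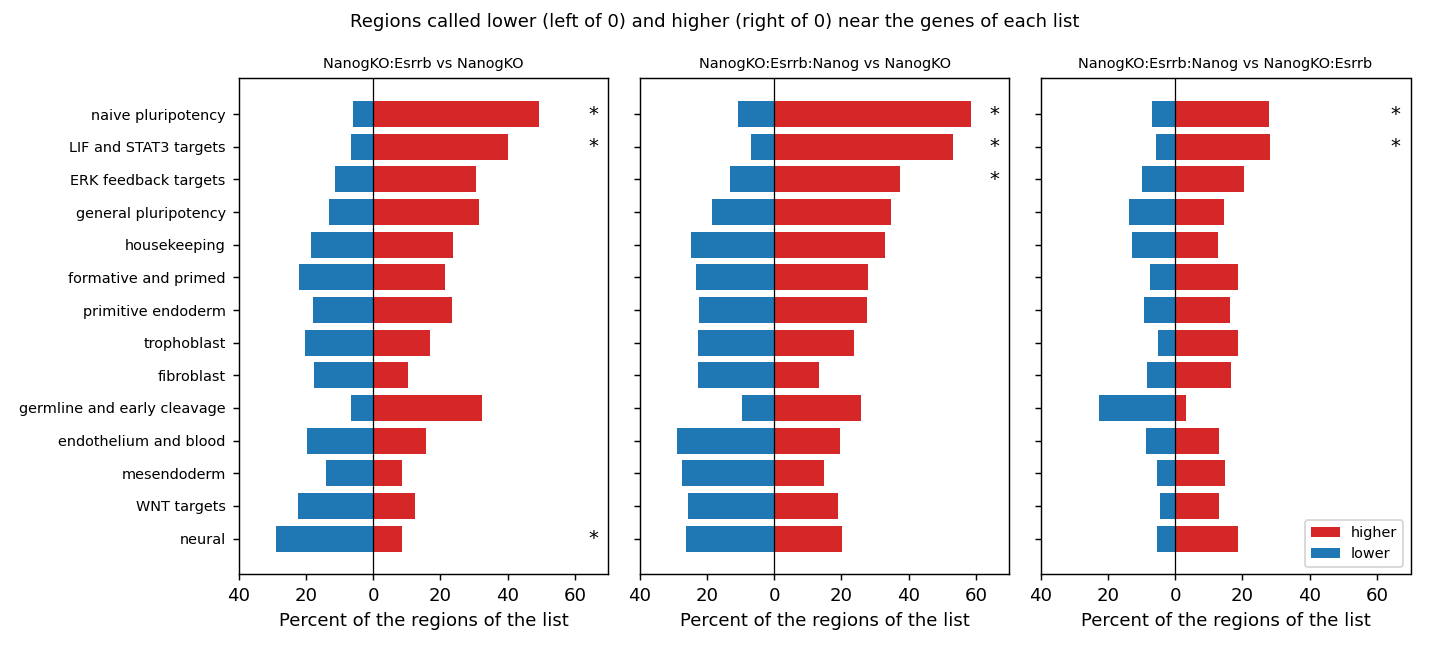
Percent of the regions of each of the 14 gene lists (y axis) called higher (red, right of 0) or lower (blue, left of 0) in the 3 comparisons (x axis); a star marks lists that passed camera with its preset correlation. With an estimated correlation, 0 of the 14 lists passed in each comparison. The naive list has 185 and 219 of 374 regions higher against NanogKO, and 104 in the comparison between the groups that carry Esrrb.

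The largest fall in both comparisons with NanogKO was in Uty (chrY:1245197-1245872), a Y-linked histone demethylase gene. It had 380 to 515 counts per NanogKO library and 0 in all 6 other libraries, so it was at least 495-fold lower in NanogKO:Esrrb and at least 414-fold lower in NanogKO:Esrrb:Nanog, with the floor set at 3 counts over a group. Of 14 Y regions below 2 Mb, 13 had 3 counts or fewer summed over these 6 libraries. The exception was a region near Eif2s3y (chrY:998554-999504) with 20 to 72 counts in each of them. Over the 14 regions, NanogKO libraries held 1735 to 2261 counts and the others 22 to 72. All 25 Y regions beyond 90 Mb had counts in every library, but whether these reads came from chromosome Y alone was not examined. Between these stretches the regions were mixed. Those with nearest genes Gm20918, Gm20873 and Gm21282 had 67 to 98, 60 to 72 and 27 to 38 counts per NanogKO library. In NanogKO:Esrrb they had 10 to 31, 15 to 18 and 0 to 1. Those with nearest genes Gm20777, Gm21805 and Gm21241 had 78 to 141, 55 to 79 and 7 to 9 in NanogKO. In NanogKO:Esrrb these had 72 to 118, 72 to 100 and 11 to 17. On the X chromosome, 2 neighbouring regions (chrX:11734560-11735194 and chrX:11735412-11735921) had 0 counts in all 6 libraries of the groups that carry Esrrb. They had 166 to 226 and 112 to 158 per NanogKO library. Their nearest protein-coding gene was Bcor, a transcriptional corepressor gene, but their distance to it is not given here, so no link to Bcor is drawn. They were at least 235-fold and 155-fold lower in NanogKO:Esrrb, and at least 196-fold and 129-fold lower in NanogKO:Esrrb:Nanog. These 2 X regions were singled out after their values were seen, and floors cover counting error only.

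**Figure D4:**
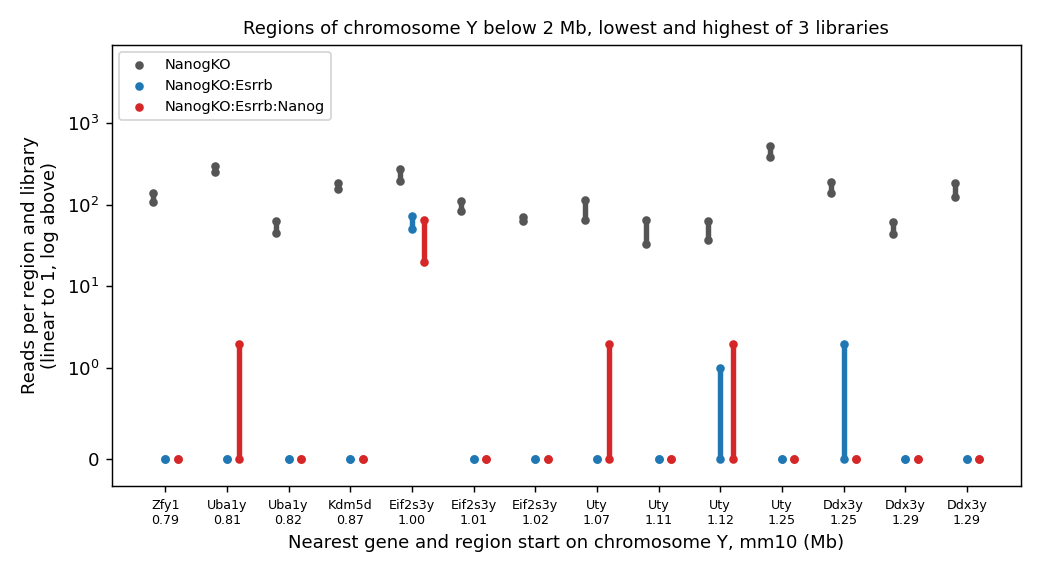
Reads per region and library (y axis, linear to 1 and logarithmic above) in the 14 chromosome Y regions below 2 Mb (x axis, nearest gene and start in Mb); each bar runs from the lowest to the highest of the 3 libraries of a group, shown by colour. The other two groups lie at or near 0 in 13 of the 14 regions, and near Eif2s3y at 998554 they hold 20 to 72 reads.

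In NanogKO:Esrrb:Nanog cells, the naive list rose furthest against NanogKO, with 219 of 374 regions higher and 40 lower (226 and 44 adjusted over the list alone; adjusted p = 3.9e-10, and adjusted p = 0.17 with an estimated correlation) and a median log2 fold change of 0.61. LIF and STAT3 targets rose, with 123 of 231 higher and 16 lower (123 and 17 adjusted over the list alone; adjusted p = 5.5e-08, and adjusted p = 0.17 with an estimated correlation). ERK feedback targets rose, with 115 of 307 higher and 40 lower (115 and 40 adjusted over the list alone; adjusted p = 0.0074, and adjusted p = 0.17 with an estimated correlation). The medians of the last 2 lists were 0.51 and 0.24. With an estimated correlation 0 of 14 lists passed camera, 3 had an unadjusted p below 0.05 and fry called 10. Among regions within 1 kb of a gene end the naive list passed, and the LIF and ERK lists had adjusted p = 0.089 and 0.22, with medians of 0.43 and 0.16. Within 10 kb of a gene 4 lists passed, these 3 and general pluripotency (higher, adjusted p = 0.018). Over the alternatives tested with camera, adjusted p ran from 5.6e-13 to 0.17 for the naive list, from 2.1e-08 to 0.17 for the LIF list and from 0.00088 to 0.22 for the ERK list. Less the regions of Esrrb and Nanog, the naive list had 190 of 324 regions higher and 35 lower (adjusted p = 1.8e-09, and 0.17 with an estimated correlation).

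The Esrrb region at chr12:86503894-86504645 rose 8.11-fold (3.02 ± 0.14, adjusted p = 1.5e-14). A region in Jam2 (chr16:84824867-84825400) rose 5.76-fold (2.53 ± 0.14, 2.1e-13), and the region near Klf5 4.15-fold (2.05 ± 0.12, 2.4e-13). The region near Cish fell 8.11-fold (-3.02 ± 0.17, 1.7e-13). Of the ERK feedback genes, a region in Etv5 (chr16:22395127-22395459) rose 4.64-fold (2.21 ± 0.14, 2e-12) and one 22316 bp from Myc, a growth regulator (chr15:62012677-62012975), rose 7.34-fold (2.88 ± 0.19, 2.1e-12). Over all regions, 39147 were higher and 38429 lower, 49.3% of those tested, and 17840 and 17396 changed by more than 2-fold. Regions with peaks only in NanogKO:Esrrb:Nanog were not counted, since the peak lists carry no peak name of that group. With library totals in place of TMM factors, the counts were 33109 and 45307 and the median over all regions moved from -0.01 to -0.10.

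The largest rises lay near Prmt8, an arginine methyltransferase (chr6:127794914-127795300, 30.1-fold, 4.91 ± 0.21), near Zc3h12a, an RNase that degrades inflammatory mRNAs (4.78 ± 0.23), in Parvb, a focal adhesion protein (4.74 ± 0.26), in Rcn1 (4.64 ± 0.27) and in Btbd11 (4.56 ± 0.25). The largest autosomal falls lay in App, the amyloid precursor gene (chr16:85128147-85128484, 33.3-fold, -5.06 ± 0.30), near Errfi1, an inhibitor of EGF receptor signalling (-4.98 ± 0.29), in Arsg (-4.92 ± 0.27) and near Ube2q2 (-4.91 ± 0.22). Single regions of other lists moved as well. The Lin28a region fell (-3.96 ± 0.25) and a region 40382 bp from Sall4 fell (-2.64 ± 0.17). The Foxd3 region rose 10.7-fold (3.43 ± 0.17). Regions in Meis2 and Pax3 of the neural list fell, 15.4-fold (-3.95 ± 0.35) and 4.57-fold. A region near Elf5, a trophoblast factor, rose (3.46 ± 0.24) and the Fgfr2 region fell (-3.61 ± 0.23). Near Gsc, a mesendoderm homeobox gene, a region rose 14.4-fold (3.85 ± 0.36), while the Lefty1 region fell (-1.66 ± 0.13). Regions near Notum and Axin2, both WNT feedback genes, rose (2.04 ± 0.15 and 2.03 ± 0.18).

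In the remaining named pairs, the Col4a2 and Lamb1 regions moved by 3.03 ± 0.21 and -2.41 ± 0.19, and those at Tcstv1 and Mael by 2.06 ± 0.18 and 2.37 ± 0.22. The Col5a1 region moved by 2.78 ± 0.18. Near Thy1 it was not the earlier region (chr9:44036785-44037487) but another (chr9:44040975-44041117) that is named here, and it fell (-2.98 ± 0.34). Regions near Cdh5 and Pecam1 moved by 2.50 ± 0.17 and -2.98 ± 0.20, and those near Actb and Eif4a2 rose by 2.36 ± 0.16 and 2.04 ± 0.14. All regions named for this comparison had adjusted p at or below 4.9e-08. The 11 lists that did not pass had adjusted p from 0.21 to 0.77. They held 74 regions higher and 39 lower for general pluripotency, 90 and 75 for formative and primed, 74 and 60 for primitive endoderm, 19 and 35 for mesendoderm, 37 and 48 for neural, and 52 and 49 for trophoblast. WNT targets had 29 higher and 39 lower, germline and early cleavage genes 8 and 3, fibroblasts 13 and 22, endothelium and blood 36 and 53, and housekeeping genes 36 and 27. These shifted by at most 3 regions when adjusted over the list alone. The trophoblast list had a median of 0.03 and a mean of -0.01, and the fibroblast list a median of 0.01 and a mean of -0.05.

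The groups with and without Nanog added to Esrrb share a cell line name and differ in the code of their titles. LIF and STAT3 targets rose further in NanogKO:Esrrb:Nanog than in NanogKO:Esrrb, with 65 of 231 regions higher and 13 lower (71 and 16 adjusted over the list alone; adjusted p = 0.002, and adjusted p = 0.29 with an estimated correlation) and a median log2 fold change of 0.21. Naive genes rose, with 104 of 374 higher and 26 lower (113 and 33 adjusted over the list alone; adjusted p = 0.0025, and adjusted p = 0.29 with an estimated correlation) and a median of 0.15. Esrrb itself, with the 23 regions given above, is in this list. Less the regions of Esrrb and Nanog, 80 of 324 naive regions were higher and 23 lower, with a median of 0.14 (adjusted p = 0.012, 0.31 with an estimated correlation and 0.063 by fry). With an estimated correlation 0 of 14 lists passed camera, 1 had an unadjusted p below 0.05 and fry called 8. Over the alternatives tested with camera, adjusted p ran from 0.00014 to 0.29 for the LIF list and from 2.5e-07 to 0.29 for the naive list. Within 10 kb of a gene 6 lists passed, all higher: these 2, formative and primed pluripotency (0.043), primitive endoderm (0.043), neural (0.04) and ERK feedback (0.0059). Within 1 kb of a gene end 6 passed, again all higher, with formative and primed at 0.011, primitive endoderm at 0.022, neural at 0.022 and trophoblast at 0.02 besides these 2. The neural list passed (higher) without NanogKO:Esrrb replicate 1 (adjusted p = 0.032), without NanogKO:Esrrb replicate 3 (0.013) and without NanogKO:Esrrb:Nanog replicate 3 (0.021), within a range of 0.013 to 0.31 over the alternatives tested with camera. NanogKO:Esrrb:Nanog replicate 3 lay between its group and NanogKO:Esrrb over all regions, at 0.561 on a scale from 0 at NanogKO:Esrrb to 1 at the other libraries of its group. Replicates 1 and 2 were at 0.912 and 1.02, each on its own such scale, whose end at 1 includes replicate 3.

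A region in Esrrb (chr12:86463234-86463387) rose 3.50-fold (1.81 ± 0.19, adjusted p = 3.4e-07), and one in Manba, a lysosomal mannosidase of the naive list, 2.52-fold (1.33 ± 0.16, 1.6e-06). Among LIF targets, a region in Sbno2 rose from 14.1 ± 0.71 to 28.5 ± 1.8 CPM (SD, n = 3; 1.02 ± 0.12, 1.8e-06) and one in Tfcp2l1, a naive factor, from 3.25 ± 0.17 to 8.45 ± 0.69 CPM (1.38 ± 0.19, 1.5e-05). The largest rises lay in Il9r, a cytokine receptor (chr11:32196062-32196542, 12.3-fold, 3.62 ± 0.20), near Tex36 (3.10 ± 0.18), in Cdh17, an intestinal cadherin (3.07 ± 0.22), 326071 bp from Trps1 (2.88 ± 0.22) and near Fam110b (2.87 ± 0.19). The largest falls lay near Cux1, a homeobox gene (-2.32 ± 0.29), Pgbd5 (-2.28 ± 0.30) and Mfge8 (-2.24 ± 0.20), in Zfp638 (-2.17 ± 0.24), and 67399 bp from Dusp4, an ERK phosphatase (-2.09 ± 0.22).

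Near Mycn and Pou5f1, which encode general pluripotency factors, regions rose (1.37 ± 0.13 and 1.02 ± 0.15). Regions near Foxd3 and Pou3f1 of the formative list rose, 3.55-fold and 2.83-fold, as did regions near Evx1 and Eomes of the mesendoderm list (0.79 ± 0.12 and 1.65 ± 0.26). In Pax6 a region rose (1.31 ± 0.15) and in Pax3 one fell (-1.60 ± 0.21). The Elf5 region rose (2.01 ± 0.21), as did one near Dlx3 (1.52 ± 0.18). The Myc region rose (1.63 ± 0.17), and so did another in Etv5 (1.04 ± 0.14). Near the WNT feedback genes Nkd1 and Axin2 regions rose (1.08 ± 0.15 and 0.90 ± 0.15). In Hnf4a a region fell (-1.38 ± 0.20) and near Dab2 one rose (1.39 ± 0.22). A second region near Mael and one near Tcstv3 fell (-1.25 ± 0.28 and -0.63 ± 0.15). Regions at Col5a1 and Col3a1 rose (0.98 ± 0.16 and 1.06 ± 0.21), as did those near Cdh5 (1.11 ± 0.16) and Actb (1.11 ± 0.15), while those near Gata1 and in Tbp fell (-1.97 ± 0.28 and -1.56 ± 0.23). Against a fold change of 1.5 rather than 0 (glmTreat), the regions at Nanog, Evx1, Axin2, Mael, Tcstv3, Col5a1 and Col3a1 did not pass, and the other regions named for this comparison did. All of them had adjusted p at or below 0.0051 in the test against 0.

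The 12 lists that did not pass within 50 kb had adjusted p from 0.056 to 0.99. They held 31 regions higher and 29 lower for general pluripotency, 60 and 24 for formative and primed, 44 and 25 for primitive endoderm, 19 and 7 for mesendoderm, 34 and 10 for neural, 41 and 11 for trophoblast and 63 and 30 for ERK feedback. WNT targets had 20 higher and 7 lower, germline and early cleavage genes 1 and 7, fibroblasts 16 and 8, endothelium and blood 24 and 16, and housekeeping genes 14 and 14. These shifted by at most 4 regions when adjusted over the list alone. The endothelium and blood list had a median of 0.01, a mean of -0.01, and opposite directions in camera and fry.

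Over all regions, 19777 were higher and 18935 lower with Nanog added, 24.6% of those tested, and 2981 and 5713 changed by more than 2-fold. The peak lists behind the regions carry peak names of NanogKO and NanogKO:Esrrb libraries only. Regions with peaks only in NanogKO:Esrrb:Nanog were therefore not counted, and these numbers leave them out. Of 9111 tested regions only in the list named for NanogKO:Esrrb:Nanog, 2141 were higher and 17 lower. Of 13548 only in the NanogKO:Esrrb list, 23 were higher and 3494 lower. Membership of a single list thus went with the direction of the calls, despite the peak names. Of the regions that rose, 61.7% lay within a gene and 18% within 1 kb of a gene end, of those that fell 43.3% and 5.6%, and of those not called 56.6% and 15.4%. Abundance differed as well, with a median log2 CPM of 2.45, 1.13 and 1.49 in these classes, and location was not separated from it. With library totals in place of TMM factors, 12765 were higher and 25391 lower, so that 33.5% of calls were higher in place of 51.1%, and the median over all regions was -0.11. Leaving out NanogKO:Esrrb replicate 3 gave 12526 higher and 12066 lower, leaving out NanogKO:Esrrb:Nanog replicate 2 gave 13175 and 12256, and leaving out NanogKO:Esrrb:Nanog replicate 1 gave 14640 and 11821. Without NanogKO:Esrrb:Nanog replicate 3, 24714 were higher and 25288 lower.

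The Nanog step was then set against the Esrrb step region by region. Of the 31482 regions higher in NanogKO:Esrrb than in NanogKO, 6313 (20.1%) rose further with Nanog and 3843 (12.2%) fell back. Of the 26741 lower regions, 4032 (15.1%) fell further and 2787 (10.4%) rose back. Independent lists of these sizes would share 3955, 3786, 3216 and 3359 regions. The Esrrb locus followed the first of these classes at chr12:86503894-86504645 (4.58-fold higher, then 0.82 ± 0.12 on the log2 scale). The covariance of the log2 fold changes of both steps was 0.045, against -0.024 in 20 simulated unchanged sets (-0.024 to -0.023), a difference of 0.069. Both steps share the 3 NanogKO:Esrrb libraries with opposite sign, which by itself favours regions that fell or rose back, and 3 libraries are too few to split. A further 10677 regions rose and 11060 fell in the Nanog step without a call in the Esrrb step.

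The deposited peak lists held 122360 intervals for NanogKO, 129086 for NanogKO:Esrrb and 138118 in the list named for NanogKO:Esrrb:Nanog, covering 52.6, 60.3 and 35.5 Mb. Of the NanogKO:Esrrb peaks, 77.0% overlapped a NanogKO peak by at least 1 bp. Of the peaks in the list named for NanogKO:Esrrb:Nanog, 79.0% overlapped a NanogKO peak and 90.3% a NanogKO:Esrrb peak. The counted regions equalled the merged union of the 3 lists, and 87127 lay in all of them. There were 16095 in the NanogKO list alone, 13586 in the NanogKO:Esrrb list alone and 9112 in the list named for NanogKO:Esrrb:Nanog alone. That last list carries peak names and scores of a NanogKO:Esrrb library only, and 89.5% of its names were also in the NanogKO:Esrrb list. Its intervals were the shortest, with a median of 179 bp against 342 and 370 bp, so overlap shares with it are not comparable to the others.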

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

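The refit on regions of all 3 peak lists and the lists less the regions of Esrrb and Nanog were added, and the distance to gene spans adopted, after seeing the data. No named region and no list that passed camera changed direction under these alternatives, while lists that did not pass did so in some. The balance of calls turned to more lower than higher with library totals (33109 and 45307 against NanogKO, 12765 and 25391 against NanogKO:Esrrb), without NanogKO:Esrrb:Nanog replicate 3 (40252 and 40922, 24714 and 25288) and with voom against NanogKO (38223 and 38315). In the main fit, calls beyond 2-fold in NanogKO:Esrrb:Nanog against NanogKO:Esrrb were also more often lower (2981 higher and 5713 lower). Of 2119 results for named regions under the alternatives, 2112 kept their call and direction and 7 lost the call, all in NanogKO:Esrrb:Nanog against NanogKO:Esrrb when tested against a 1.5-fold change. These regions were named for a small p or a large change in the same libraries, so keeping the call was likely from the outset. It says little about the other called regions. Counts are given as higher and lower, for NanogKO:Esrrb against NanogKO, NanogKO:Esrrb:Nanog against NanogKO, and NanogKO:Esrrb:Nanog against NanogKO:Esrrb in turn. Against a 1.5-fold change they were 11974 and 8644, 18575 and 16815, and 1760 and 1384. At adjusted p under 0.01 they were 22757 and 17593, 30515 and 28280, and 10298 and 8486. In regions of all 3 lists, where fewer regions were tested, they were 14981 and 10741, 19755 and 18167, and 9577 and 9516. Each library left out in turn gave 25620 to 28606 higher and 20533 to 23133 lower, 34155 to 40252 and 32807 to 40922, and 12526 to 24714 and 11821 to 25288. With the replicate block, the counts were 33834 and 29737, 41567 and 40940, and 23512 and 22243, and apart from the 3 lists gained in the first comparison it changed no list call. Apart from the 12765 with library totals, the other scalings, tools and filters stayed within 1.5 times.

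Of the 14 lists, 3, 3 and 2 passed camera at its preset correlation. With an estimated correlation 0, 0 and 0 passed camera, 2, 3 and 1 had an unadjusted p below 0.05, and fry called 11, 10 and 8. Within 10 kb, 7, 4 and 6 passed, and within 100 kb 4, 3 and 2. Less the regions of Esrrb and Nanog, the same 3, 3 and 2 passed. Within 1 kb of a gene end 0, 1 and 6 passed camera, which was run alone there, and 3, 3 and 7 had an unadjusted p below 0.05. With the replicate block, 6 passed in the first. Leaving out each library gave 3 to 5, 3 to 3 and 2 to 3. The cause of these moves was not tested. Fewer regions were counted near gene ends, but there the lists passing fell from 3 to 0 and from 3 to 1 and rose from 2 to 6. Requiring 50% of both lengths, the overlap of NanogKO:Esrrb peaks with NanogKO went from 77.0% to 68.0%, of the list named for NanogKO:Esrrb:Nanog with NanogKO from 79.0% to 43.1%, and with NanogKO:Esrrb from 90.3% to 43.6%. At or above the median score they were 80.6%, 85.6% and 98.6%. Corrections for GC content, alone or with the block, and both motif alternatives were not run.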

Other observations

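The genes with many regions moving together, the 2 Mb bins, and the tests of chromosome Y, of lower signal, of the region set and of what a mixture or added background would give were chosen only after results were seen.

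Among 5956 genes with at least 8 regions, Ak4, a mitochondrial adenylate kinase gene, had 23 of 23 regions higher in NanogKO:Esrrb than in NanogKO, with a median log2 fold change of 1.44. Epha4, an ephrin receptor gene, had 40 of 45 higher (median 1.38), and Pcsk6, a proprotein convertase gene, 26 of 30 (1.36). Bmp4, a growth factor gene, had 14 of 18 higher (1.41). The imprinted neighbours Rtl1 and Dlk1 fell, with 20 of 22 regions lower (-1.58) and 10 of 13 lower (-1.09). In Notch2, 5 of 9 regions fell, and the median over the 9 was -1.42.

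In NanogKO:Esrrb:Nanog against NanogKO, Il6ra, which encodes the interleukin 6 receptor, had 12 of 13 regions higher (2.12), and Metrnl, a secreted factor gene, 7 of 8 lower (-2.34). In NanogKO:Esrrb:Nanog against NanogKO:Esrrb, 10 of the 13 Il6ra regions were higher (0.80), as were 12 of 15 at Mras, a RAS family gene (0.95), and 9 of 16 at Lama1, a laminin gene (0.56). Slc40a1, which encodes the iron exporter ferroportin, had 6 of 9 lower (-0.92). Stretches of 2 Mb were examined over all regions, those of the genes above included, so their counts are not separate from the counts per gene. Of 82 regions on chromosome 1 from 76 to 78 Mb, 53 were higher in NanogKO:Esrrb than in NanogKO (median 0.97). Of 179 on chromosome 4 from 100 to 102 Mb, 134 were higher (0.80). Others fell, with 17 of 28 regions lower on chromosome 7 from 58 to 60 Mb (-0.71) and 29 of 43 on chromosome 11 from 36 to 38 Mb (-0.64).

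In both groups that carry Esrrb, 13 of 14 chromosome Y regions below 2 Mb were at or near 0 counts. So were 2 regions on chromosome X whose nearest protein-coding gene was Bcor. If closed chromatin on a chromosome that is present were the cause, autosomal regions that fell would also reach 3 counts or fewer over the 6 libraries, and 0 of 23734 with at least 50 counts in every NanogKO library did, which allows a share of up to 0.016% (95% exact limit). That argues against closing of the degree seen on autosomes as the source. Most falls were small, with 9463 of all 26741 lower regions beyond 2-fold, and the closing of a whole chromosome was not modelled, so it was not excluded. The limit also treats regions of the same libraries as independent. Missing chromosome Y sequence and a deletion at the 2 X regions, in the cell line that both groups share by label, remain open as candidate explanations. They were not tested in DNA, and how much of chromosome Y might be missing was not tested. These losses cannot be separated from the Esrrb label, since no library of that line without Esrrb was analysed.

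NanogKO:Esrrb:Nanog replicate 3 lay at 0.561 between NanogKO:Esrrb (0) and its group's other libraries (1). Values of replicates 1 and 2 on such a scale were each set against the other libraries of the group, replicate 3 included. Lower signal over background would also pull replicate 3 back along the axis from NanogKO to NanogKO:Esrrb, where it stood at 1.085 against 1.058 and 1.099. Even background that gives 0.561, spread alike per region or per bp, would have put it at 0.972 or 0.965 there. It would also leave the 20% most abundant regions at 0.903 or 0.858, and they were at 0.498, against 1.011 and 1.074 in replicates 1 and 2. The axis and the most abundant regions argue against even background as the whole source, while a part in it was not excluded. Replicate 3 had 23 regions at 0 counts against 102 and 243 in replicates 1 and 2, as lower signal would give, but NanogKO:Esrrb libraries had 16 to 21, so a likeness to them would give it too. If part of its cells were like NanogKO:Esrrb cells, or all were shifted towards them, regions that rise and regions that fall would be placed alike. They were at 0.597 and 0.487, a difference of 0.11, under the bound of 0.15 and against -0.041 and 0.025 in replicates 1 and 2. That prediction was wrong for a mixture, which adds counts. On the log2 scale a mixture with the same median position would itself place rising regions 0.128 further than falling ones. The test was therefore void and decides nothing, and a mixture and a shift of every cell were not separated. A loss of added Nanog in some cells was not tested.

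About as many regions rose as fell in NanogKO:Esrrb:Nanog against NanogKO:Esrrb, 51.1% of calls being higher. This balance holds for all calls and depends on the size of the change. Among calls beyond 2-fold, 2981 were higher and 5713 lower, while tested against a 1.5-fold change 1760 were higher and 1384 lower. The list named for NanogKO:Esrrb:Nanog carries peak names of a NanogKO:Esrrb library, and 0 of its intervals carry one of its own group. The region set therefore lacks regions with peaks only in NanogKO:Esrrb:Nanog. Whether this lack sets the balance was examined. In regions of all 3 lists, 63.3% of calls were higher with the scaling of the whole set. Refitted on those regions alone, 50.2% were higher, so the scaling sets the balance and the test decides nothing. This reading was settled after both values were known.

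For each comparison, the 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. In edgeR fits of the 6 libraries alone, the real split called 66252 regions in NanogKO:Esrrb against NanogKO, 73735 in NanogKO:Esrrb:Nanog against NanogKO and 33750 in NanogKO:Esrrb:Nanog against NanogKO:Esrrb, so 1 of 10 splits was as large each time. The highest of the other splits called 0 regions in each comparison, with 376 to 2915, 411 to 5258 and 839 to 10154 regions at an unadjusted p under 0.05 among them, against 78001, 83626 and 55636 in the real splits. Every other split holds libraries of both groups on each side. That puts the difference between the groups into the spread, so few or no calls were likely from the outset. Other tools were not run on the splits. In the 2 comparisons whose replicate numbers were taken to pair the libraries, 3 other splits part all 3 pairs as the real one does. Each called 0 as well, but they also hold both groups on each side, so the splits decide nothing.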
